A study of Linum usitatissimum with 11 samples.

How the data were processed

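Transcript levels were measured in peeled inner stem tissue of field-grown flax (Linum usitatissimum, cultivar Diane) at the vegetative stage, in 3 wild-type (wt) plants and 6 plants of the lbf1 mutant family, on 11 arrays. Per the labels, lbf1 is a chemically induced (EMS) mutant family, total RNA was extracted with TriReagent, and it was labelled with Cy3 by Agilent's 1-colour protocol. Plant 3 of the wild type and plant 1 of the mutant were each hybridised to 2 arrays, so 4 arrays held wild-type RNA and 7 held mutant RNA. The plants are separate individuals per the labels, and the titles of mutant plants 5 and 6 read lbf in place of lbf1 although their genotype label is the same.

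Each deposited scanner table holds spot intensity in linear brightness units, per the file headers with no normalization. The header of the array of wild-type plant 1 gives GenePix Pro 6.0.1.22, 532 nm and a photomultiplier gain of 450. The gain of the other arrays was not compared here. The same deposited tables give the percent of saturated pixels of each spot and GenePix flag codes, where -50 marks a spot not found and -100 a bad spot. The authors' deposited value table of the whole series is on the log2 scale. Its scale was found by setting it against the scanner tables: at least 99.99% of its values on every array equal, within 0.001, log2 of the spot median minus local background plus 1 constant per array. All 11 of its columns have a median of 9.02, and values are missing where GenePix flagged the spot as bad or not found. Direction and scale of that table are therefore known, and the reason for its centring is not given in the sources used here.

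Every array carried 45220 spots, of which 1765 were controls and 43455 were probes with 1 spot each. Of the probes, 43408 carry gene model identifiers starting with Lus and 47 carry contig identifiers. The tables pair no identifier with a gene name or function. The gene lists fixed before the data were examined (wall polymers, lignin, hormone and stress pathways, and markers of outer and vascular tissues) therefore could not be matched, and no gene list test was run. For the same reason only 2 probes that rose and 2 that fell are named, by identifier.

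The design fixed before the data were examined assumed Agilent Feature Extraction signals scaled to the 75th percentile. The tables hold GenePix intensities instead, so the background was corrected with normexp (offset 50) on the spot mean and the local background median, and arrays were brought to a common distribution by quantile normalization. Scaling to the 75th percentile became an alternative. Control spots were removed after normexp and bad spots were set to missing. Fold changes are on this log2 scale with its offset, which understates changes of dim probes.

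A probe was above background on an array if its net signal (spot mean minus local background) exceeded 2.6 SDs of the local background. It was tested if it was above background on all arrays of a plant in at least 3 plants. This left 28267 probes tested and 15188 untested. Arrays of a plant were averaged first. Genotypes were compared with limma 3.58.1 (lmFit and eBayes, in R 4.3.3) with no block, and probes with a Benjamini-Hochberg adjusted p under 0.05 were called. A further count took called probes that differed by at least 2-fold. The naming rule took called probes with every mutant plant on the same side of all 3 wild-type plants, and among them those with the greatest rise and fall. Only probes above background on at least 1 array of each genotype and not saturated on all arrays of either were ranked. A probe above background on every array of a genotype and on no array of the other has only a bound on that other side. Its fold is given as "at least", taking for each dim array the higher of its lowest signal above background and the probe's own value. A spot was called saturated when at least 50% of its pixels were.

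The spread between plants was the root mean square log2 difference of each plant from the other plants of its genotype over tested probes. Group means of it were compared with an exact two-sided permutation test. These values share plants within a genotype, so that p is approximate. Brightness of a plant is log2 of the upper quartile of net signal. Flax signal over spike-in is that quartile over the mean log2 signal of 4 E1A spike-in probes that lay between 100 and 20000 units on every array.

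Between 54.7% and 64.7% of probes were above background per array. Arrays give no counts, and precision is limited by the number of arrays. The comparison was tested on simulated data with 28267 probes, 200 of them changed. Of these, 66.0% were called at a log2 change of 1 with 7 false calls, 89.5% at 2 with 10 false calls, and 0 at 0.5 with 0 false calls. These shares do not carry over to the data, where 9114 probes were called, because the adjusted p is stricter when few probes change. The simulated noise was independent between probes and plants, and no slide or brightness effect was simulated.

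The arrays came from 4 slides, and slide and scan batch divide them identically. Slide 1 held wild-type plants 1 and 2 and both arrays of mutant plant 1. Slide 2 held mutant plants 2 to 5, slide 3 held mutant plant 6, and slide 4 held both arrays of wild-type plant 3. Alternatives covered scaling, background correction, the filter on dim probes, the authors' values, the treatment of repeat arrays, blocks for slide and plant number, array weights, the variance prior, brightness as a term, and leaving out each plant in turn.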

Results

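Transcript levels were compared between the inner stem tissues of 3 wild-type flax plants and 6 lbf1 plants. Bast fibres of flax, the source of linen, have thick cellulose-rich walls with little lignin, and lbf1 is named for bast fibres that lignify. The tissue measured here is what remains inside the stem after peeling. The question stated by the design is which transcripts differ in this inner tissue between mutant and wild type. Signal was above background for 23767 to 26591 probes on the 4 wild-type arrays and for 27046 to 28120 probes on the 7 mutant arrays. Upper-quartile net signal was 317 to 732.5 units on wild-type arrays and 650 to 920 units on mutant arrays. The repeat arrays of wild-type plant 3 were the dimmest and the brightest of the wild type, at 317 and 732.5 units.

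Of 28267 probes tested with limma, 9114 (32.2%) differed between genotypes, 4726 of them higher and 4388 lower in lbf1. The median change was 0.69 log2 among the probes that rose and -0.81 log2 among those that fell, beside a median standard error of 0.157 log2 over all tested probes. The change was at least 2-fold for 3066 of the called probes. All 6 mutant plants lay beyond all 3 wild-type plants for 4239 of the probes that rose and 3970 of those that fell. Over all tested probes this complete separation held for 34.4%, against 2.38% given by chance. Among the 47 contig probes, 28 were tested and 12 were called.

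The larger rises outnumbered the larger falls. Among called probes above background on at least 1 array of each genotype and not saturated on all arrays of either, 1182 rose and 1546 fell by at least 2-fold. At 4-fold or more, 339 rose and 251 fell. At 8-fold or more, 121 rose and 34 fell, and at 16-fold or more 38 rose and 3 fell. At 32-fold or more there were 16 probes that rose and 1 that fell. Some of these probes were above background on few arrays of the dimmer genotype, so their folds are uncertain. Among called probes above background on every array, 698 rose and 1061 fell by at least 2-fold, and 55 rose and 20 fell by at least 8-fold.

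**Figure D1:**
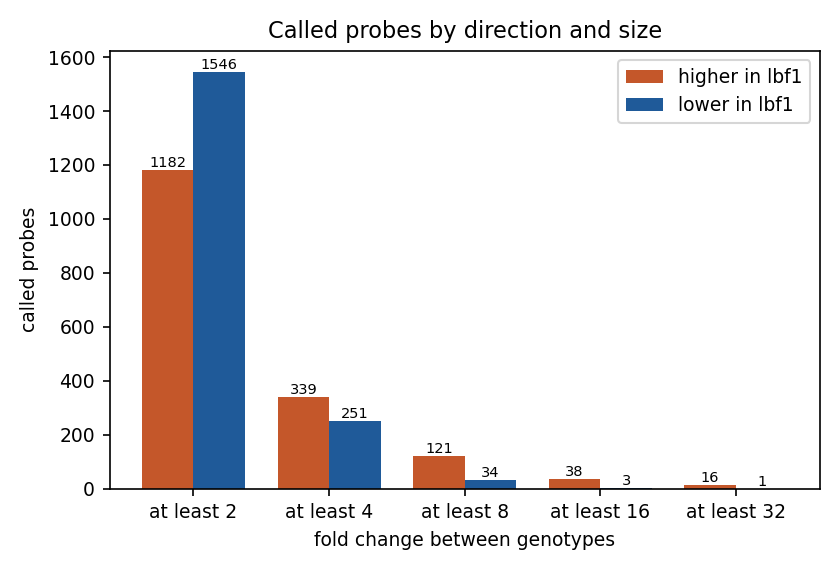
Number of called probes above background on at least 1 array of each genotype (vertical axis) that changed by at least the fold on the horizontal axis, split by direction. Falls outnumber rises at 2-fold or more (1546 against 1182), and rises outnumber falls at 8-fold or more (121 against 34).

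The balance of smaller rises and falls depended on how arrays were scaled. Of the called probes, 51.9% rose after quantile normalization, 36.8% after scaling to the 75th percentile and 58.2% after scaling to the median. In the authors' own values 68.3% rose. Those values also differ in background correction, in missing spots and in the probes tested (23544), so that share is not an effect of scaling alone. The median change over tested probes was 0.02 log2 after quantile normalization, -0.097 log2 after scaling to the 75th percentile and 0.061 log2 after scaling to the median. In the authors' values this change was 0.17 log2. It was 0.65 log2 after scaling to spike-in probes, where 93.9% of called probes rose. Over all called probes, with those not above background on any array of a genotype included, 200 rose and 35 fell by at least 8-fold after quantile normalization. Counted from the median change instead, these were 195 and 37. With scaling by 1 constant per array these counts were 175 and 39, whichever constant was used, since a constant leaves changes relative to the median as they are.

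Slide 1 alone held plants of both genotypes. Within slide 1 alone, comparing mutant plant 1 with wild-type plants 1 and 2, 7944 probes were called, 3863 higher and 4081 lower. There the spread rests on the wild-type pair alone, and the lone mutant plant was assumed to vary as that pair did. With slide as a fixed block, 4798 probes were called, 2362 higher and 2436 lower in lbf1. Its changes are again those of mutant plant 1 against wild-type plants 1 and 2, since the other slides hold a single genotype and add to the estimate of spread only. With slide as a random block, which uses all 9 plants, 8559 were called. Without slide 1, which left mutant plants 2 to 6 against wild-type plant 3 as the lone wild type, 3661 were called, and wild-type plant 3 was then assumed to vary as the mutants did. Across 28204 probes, the difference within slide 1 and the difference on the other slides correlated with Pearson's r of 0.802 and Spearman's rho of 0.708, where probes are not independent replicates. Plants also differed in brightness by genotype, from 8.72 to 9.07 log2 in the wild type and from 9.34 to 9.85 log2 in lbf1. With brightness as a term beside the genotype 101 probes were called, and genotype and brightness had a correlation of 0.909. Over the 9114 probes called without that term, the median change in the direction first found was 0.75 log2 without it and 0.64 log2 with it, while the median standard error went from 0.155 to 0.369 log2.

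The first principal component separated the genotypes, which also differ in brightness. It held 60.1% of the variance and placed the wild-type plants between -84.95 and -83.19 and the mutant plants between 27.5 and 56.5. The second held 12.4% and spread the mutant plants from -37.74 to 52.1, with wild-type plants from -8.92 to 3.29. Wild-type plants 1 and 2 on slide 1 lay beside wild-type plant 3 on slide 4, and mutant plant 1 on slide 1 lay on the side of the other mutant plants, the farthest from the wild type at 56.5. Among the mutant plants, plant 2 had the lowest score and the lowest brightness.

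**Figure D2:**
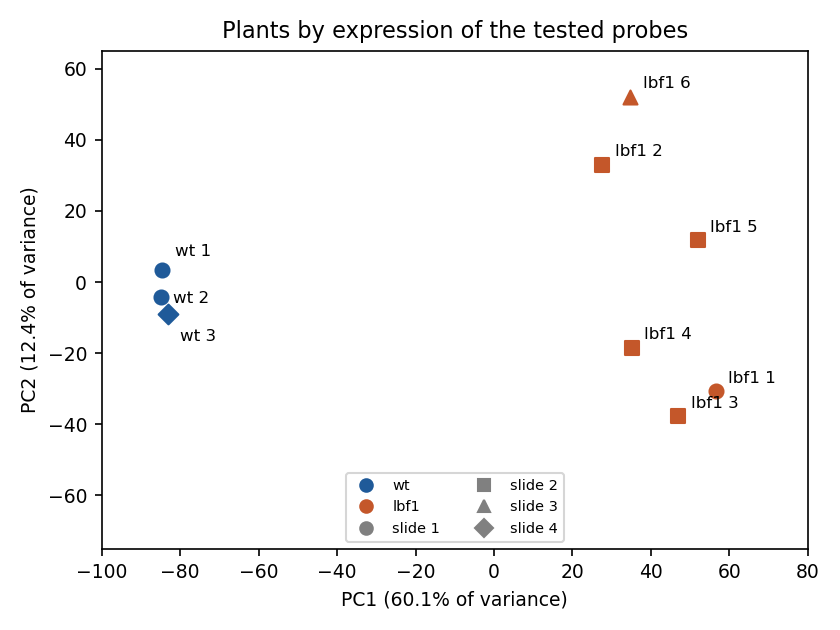
Each point is a plant placed by its scores on the first (horizontal, 60.1% of variance) and second (vertical, 12.4%) principal components of the tested probes, with colour for genotype and shape for slide. The 3 wild-type plants lie between -84.95 and -83.19 on the first component and the 6 mutant plants between 27.5 and 56.5, whichever slide they were on.

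Among the probes ranked for naming, the greatest rises were those of Lus10003265 and Lus10006302. The level of Lus10003265 was 6.54 ± 0.384 log2 (SD, n = 3) in the wild type and 15.7 ± 0.145 log2 (SD, n = 6) in lbf1. This is a log2 change of 9.16 with a standard error of 0.163 and a limma adjusted p of 2.9e-09. It was above background on 1 of 4 wild-type arrays and on 7 of 7 mutant arrays, and saturated on 3 of the mutant arrays. Lus10006302 stood at 6.65 ± 0.379 log2 (SD, n = 3) in the wild type and 15.7 ± 0.399 log2 (SD, n = 6) in lbf1. Its log2 change was 9.06 (standard error 0.248, limma adjusted p of 5.62e-08). It too was above background on 1 wild-type array, and it was saturated on 5 of the 7 mutant arrays. Both wild-type levels were close to the lowest signal above background (6.19 log2 on average) and both mutant levels close to the top of the scanner's range, so the true ratios of these probes are poorly bounded above.

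Among the probes ranked for naming, the greatest falls were those of Lus10038721 and Lus10014569. Lus10038721 was at 14.3 ± 0.832 log2 (SD, n = 3) in the wild type and 9.12 ± 1.36 log2 (SD, n = 6) in lbf1, a change of -5.18 log2 (standard error 0.738, limma adjusted p of 0.000708). Among the mutant plants it ranged from 6.74 log2 in plant 5 to 10.17 log2 in plant 2, and it was above background on all 11 arrays. The call of Lus10038721 was lost without slide 1 (-4.04 log2, limma adjusted p of 0.0854) and with brightness as a term (-2.19 log2, limma adjusted p of 0.561). Lus10014569 was at 11.1 ± 0.311 log2 (SD, n = 3) in the wild type and 6.19 ± 0.261 log2 (SD, n = 6) in lbf1, a change of -4.89 log2 (standard error 0.183, limma adjusted p of 3.67e-07). It was above background on 3 of 7 mutant arrays, so its lower level lies near the floor. The calls of Lus10003265, Lus10006302 and Lus10014569 held with slide as a random block and with brightness as a term. Sizes near the floor or the ceiling moved with the processing. With background subtraction and scaling to the 75th percentile Lus10014569 changed by -7.02 log2 and Lus10038721 by -5.69 log2, which turns the order of these falls, and Lus10003265 and Lus10006302 by 10.55 and 10.25 log2. With brightness as a term Lus10006302 changed by 7.71 log2.

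**Figure D3:**
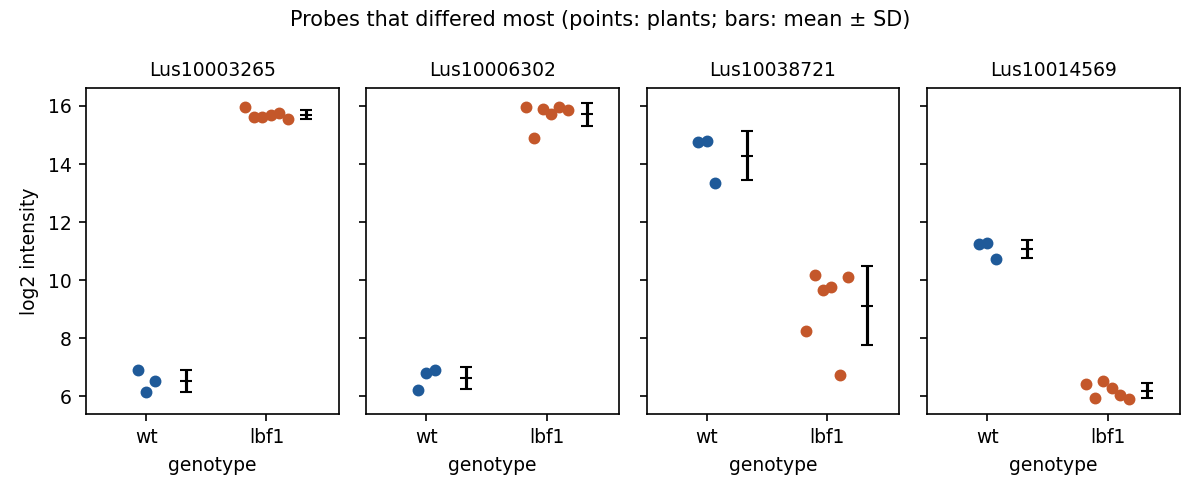
Log2 intensity (vertical axis) of the 2 probes that rose most and the 2 that fell most among those ranked for naming, by genotype. Each point is a plant, with bars for the mean ± SD beside them. The rising probes sit near 6.5 log2 in the 3 wild-type plants and near 15.7 log2 in the 6 mutant plants, and Lus10038721 varies most among the mutant plants, from 6.74 to 10.17 log2.

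Many probes were seen in the mutant alone. Of all 43455 probes, 376 were above background on all 7 mutant arrays and on no wild-type array, and 23 were above background on all 4 wild-type arrays and on no mutant array. The difference was called for 318 of the former and for all 23 of the latter. Both sets were chosen on these same arrays, so such calls are no separate support. Probes seen in lbf1 alone were higher there by a median of at least 2.32-fold, with 216 at least 2-fold, 119 at least 4-fold, 27 at least 16-fold and 5 at least 64-fold higher. The highest bound was at least 254-fold. Some lay at the detection limit and were not higher in lbf1, such as Lus10028591 with 6.75 log2 there and 6.90 log2 in the wild type. Probes seen in the wild type alone were higher there by a median of at least 2.46-fold, 4 of them by at least 4-fold, and the highest bound was at least 7.62-fold. Without wild-type plant 3, whose arrays were the dimmest and the brightest of the wild type, the counts were 704 and 77. Without its dimmest array alone they were 404 and 38. With the first array of each plant, which drops the brightest wild-type array and 1 array of mutant plant 1, they were 620 and 30. Without wild-type plant 1 or 2 the former count was 443 or 441, and without wild-type plant 1 the latter was 36. The median level of the mutant probes was 7.20 to 7.80 log2 in the 6 mutant plants and 6.07 to 6.11 log2 in the 3 wild-type plants, a gap that their choice favours.

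**Figure D4:**
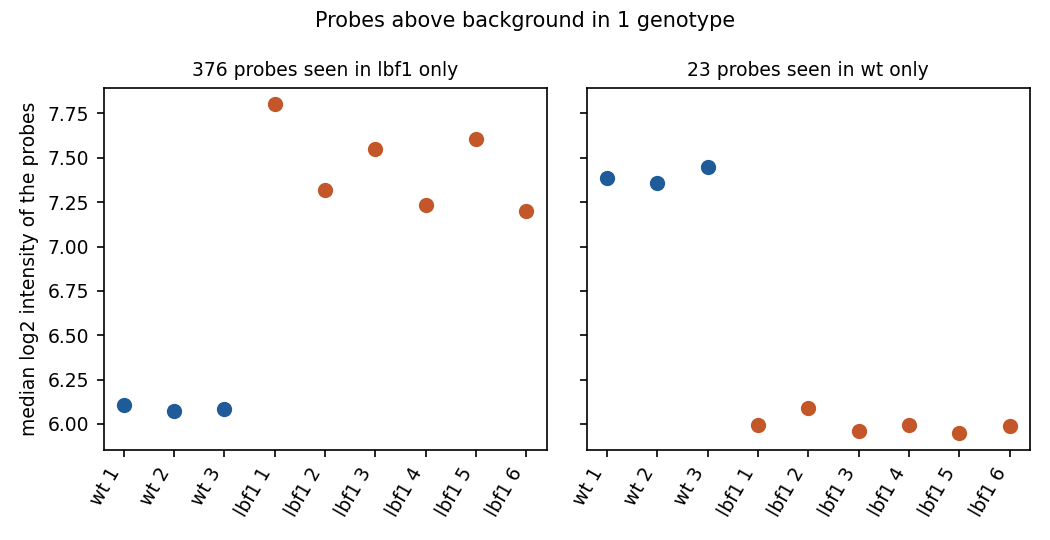
Median log2 intensity (vertical axis) per plant of the 376 probes seen in lbf1 alone (left) and the 23 probes seen in the wild type alone (right), with a point per plant coloured by genotype. The left set lies between 7.20 and 7.80 log2 in mutant plants and near 6.1 log2 in wild-type plants, and the right set lies between 7.36 and 7.45 log2 in wild-type plants and near 6.0 log2 in mutant plants. Both sets were chosen by detection on these same arrays.

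The spread between plants within a genotype was 0.435 ± 0.0341 log2 (SD, n = 3) in the wild type and 0.489 ± 0.0261 log2 (SD, n = 6) in lbf1. The difference of 0.05 log2 had p = 0.0476 in an exact two-sided permutation test over 84 splits, where the smallest p possible was 0.0119. This call was lost without any one of wild-type plants 1 and 2 (exact permutation p = 0.464 and 0.571) or of mutant plants 1, 2, 5 and 6 (exact permutation p = 0.0714, 0.143, 0.0536 and 0.214). It was also lost with no filter on dim probes (exact permutation p = 0.881) and with a single array per plant (exact permutation p = 0.952). On slides that held several plants of a genotype, the wild-type pair differed by 0.346 log2 and the 6 mutant pairs by 0.363 to 0.541 log2, which leaves 1 wild-type value and no test. Repeat arrays of a plant differed by 0.265 log2 for mutant plant 1 and by 0.449 log2 for wild-type plant 3, whose own differences from the other wild-type plants were 0.470 and 0.478 log2. Pairs of plants of different genotype differed by 0.779 to 0.945 log2, more than any pair within a genotype (at most 0.594 log2).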

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

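The test of slide, the fit with brightness as a term and the use of the repeat arrays of wild-type plant 3 were chosen after the data were seen, the first after its own result, and so was the comparison of mutant levels with the wild-type floor. Mutant plant 1 had 24951 probes above background on all its arrays, and the nearest other mutant plant had 27046. That plant has 2 arrays and the others 1, so its count asks for more by construction. The level of Lus10006302 in mutant plant 2 was 14.9 log2, and the nearest other mutant plant was at 15.7 log2. The median level of the probes seen in the wild type alone was 6.09 log2 in mutant plant 2, and the nearest other mutant plant was at 5.99 log2. These stood apart among 13 measures examined over the 6 mutant plants, and chance alone marks about 1 in 20 such measures. Flax signal relative to spike-in probes, a measure outside the genotype comparison, was higher in lbf1 than in the wild type by 0.81 log2, with -0.89 ± 0.148 log2 (SD, n = 3) in the wild type and -0.08 ± 0.2 log2 (SD, n = 6) in lbf1. Its exact two-sided permutation p was 0.0119, the smallest that 84 splits can give. Within slide 1 the difference was 0.73 log2, and the repeat arrays of wild-type plant 3 differed by 1.71 log2 in the same measure. They read -1.905 and -0.2 log2, the second above mutant plant 2 at -0.43 log2. The separation behind this p therefore rests on averaging these 2 arrays.

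In 1 of the 84 splits of the 9 plants into 3 and 6, the real split, as many as 9114 probes were called, and the highest of the others called 193. This is the smallest share that 84 splits can give, which argues against chance without excluding it. Of the 3661 probes called without slide 1, 96.6% had the same direction within slide 1, which argues against slide as the whole cause. Brightness stays open: with it as a term 101 probes were called. This is below the 193 of the highest other split, which comes from fits without the term. Brightness as the cause would give this outcome, but so could a genotype effect at the larger standard error, so the count cannot decide. The correlation of 0.909 between brightness and genotype raised the median standard error of the 9114 called probes from 0.155 to 0.369 log2. Their median change in the direction first found went from 0.75 to 0.64 log2. Among the mutant plants brightness also correlated with the score on the first principal component (Pearson's r of 0.845), a relation examined after the scores were seen. With the term 96.0% of the 9114 probes kept their direction, but they were chosen in the same plants, so this share decides little. Against brightness as the whole cause, 89.98% of the probes called without wild-type plant 3 and mutant plant 2 kept their direction between 2 arrays of these plants. These were the brighter array of the former and the dimmer array of the latter. The repeat arrays of wild-type plant 3, 1.21 log2 apart in brightness, differed by a root mean square of 0.449 log2 over the tested probes. Plants of different genotype differed by 0.779 to 0.945 log2. These array comparisons rest on 1 or 2 plants.

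Of the 376 probes seen in lbf1 alone, 83 stood in every mutant plant above the highest floor or own value of the wild-type arrays by more than 1.54 log2, the widest gap in brightness between a mutant and a wild-type array, which argues against dim wild-type arrays as the cause for these 83. For the other 293 brightness stays open. A wider set of 653 probes was chosen without the array of mutant plant 2 (650 units) and the second array of wild-type plant 3 (732.5 units). They were seen on all other mutant arrays and on no other wild-type array. The array of mutant plant 2 showed 564 and the brighter wild-type array 224, which is 39.7% of that share. This is under what dimness was held beforehand to allow, but a single array of a single plant does not exclude dimness. The first array of wild-type plant 3 also helped to choose the set, which favours a low share on its second array. For a single source of foreign RNA in varying amount, a common shift per plant held 21.5% of the variance of these probes between mutant plants (median SD 0.43 log2, against 0.21 log2 in level-matched lists) and 47.1% in the part at least 4-fold higher. The first share lies below the bound of 25% set beforehand for excluding such a source and the second does not, and noise of dim probes may lower the first, so this source stays open together with a gain of expression or a difference in DNA sequence, neither of which was tested.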

How the results depend on the processing

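The alternatives chosen after seeing the data are background subtraction with scaling to the 75th percentile, spike-in scaling, brightness as a term, slide as a random block, slide 1 alone or left out, the first array of wild-type plant 3 left out, and other detection rules. The count of called probes stayed within 1.5 times under 22 settings and moved under 6. With probes above background on every array, 6068 were called (2987 higher, 1774 at least 2-fold), where fewer were tested (17486). With slide as a fixed block, where the change is that of slide 1 alone, it was 4798 (2362 higher, 2436 lower), and without slide 1 it was 3661 (1682 higher, 1979 lower), where fewer plants were compared. With brightness as a term it was 101 (71 higher, 30 lower, 101 at least 2-fold), where the median change of the probes called without it went from 0.75 to 0.64 log2 and their median standard error from 0.155 to 0.369 log2. Spike-in scaling gave 18150 (17042 higher, 1108 lower, 6812 at least 2-fold), because flax signal over spike-in was higher in lbf1. Background subtraction together with scaling to the 75th percentile gave 4728 at least 2-fold, against 3222 with that scaling after normexp, and the cause was not tested. With plant number as a replicate block the count was 4386 (2245 higher, 2141 lower). Same-numbered plants of the genotypes had correlations of 0.0592, -0.0927 and 0.0833, and no wild-type plant correlated best with its own number. With 3 wild-type plants this check cannot decide whether the numbers pair plants. The block leaves plants 4 to 6 outside the comparison. Leaving out each plant gave 6565 to 9114 called probes, 3245 to 4689 higher, 3307 to 4425 lower and 2875 to 3190 at least 2-fold, and 70.2% to 92.5% of the 9114 called probes were called again. Scan batch gives the same division as slide and was not run separately, and gene lists were not run because identifiers have no names here.

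The counts of probes seen in lbf1 alone and in the wild type alone were 376 and 23. They were 620 and 30 with a single array per plant, 638 and 63 for spots found by GenePix, 441 and 38 at 5 background SDs, 461 and 40 without the plants titled lbf, and 404 and 38 without the first array of wild-type plant 3. Leaving out each plant gave 397 to 704 and 26 to 77, as fewer arrays must meet the rule. The difference in spread between plants (0.05 log2) kept its sign under all 19 settings run for it and its call under 7. It was not called with no filter on dim probes (0.00200), the authors' values (0.0756), a single array per plant (0.00159), without the plants titled lbf (0.0322), with background subtraction and scaling to the 75th percentile together (0.0215) and without the first array of wild-type plant 3 (0.0408), and the cause was not tested. Leaving out each plant gave 0.0113 to 0.143. Lus10003265, Lus10006302 and Lus10014569 stayed called in the same direction under every setting that measured them, and Lus10038721 lost its call without slide 1 and with brightness as a term. Signal over background limits the risers in the wild type, where they were above background on 1 of 4 arrays.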

Other observations

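The correlation between consecutive identifiers was noticed in these data before its permutation test was chosen. Genes with neighbouring identifiers changed together more than distant ones. Over 19176 pairs of tested probes with consecutive numbers, the log2 changes correlated with r of 0.139 and rho of 0.0993 across probes, which are not independent replicates. At a distance of 2 in number r was 0.0670, at 3 it was 0.0259, and at 10 it was 0.00653. Among 2130 pairs of consecutive probes that were both called, 61.3% changed in the same direction, against 50.1% expected from the share of rises. In 10000 shuffles of the changes over identifiers, p was 1e-04, the smallest that this permutation can give. Of the 376 probes seen in lbf1 alone, all tested, 375 carry gene model numbers. These formed 6 consecutive pairs, where 10000 level-matched random lists formed 3.52 on average and at most 12 (permutation p = 0.1).

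For the correlation between consecutive numbers, a spatial trend on the arrays was tested. Adjacent spots had changes correlated with r of 0.00962 over 35671 pairs, and 0.219% of consecutive numbers lay within 5 spots of each other in both directions, which argues against a trend across the slide. Deviations of single mutant plants from the mutant mean had a median r of 0.0754 between consecutive numbers, with a range of 0.0653 to 0.0880, and those of wild-type plants had r of 0.0312 to 0.0713. This is consistent with neighbours that vary together in any contrast, of which the genotype difference may be a larger instance. Whether the neighbours are copies alike enough to bind the same transcripts, or separate genes regulated together, stays open, since probe sequences and gene positions were not used here.

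Among the 6 mutant plants, brightness and the score on the first principal component correlated with Pearson's r of 0.845 (exact permutation p = 0.0278) and Spearman's rho of 0.8286 (exact permutation p = 0.0583). Without the plants farthest from the median brightness, 2 and 5, r was 0.716. Within slide 2, which held only 4 of these plants, r was 0.985 and was not tested, and the other slides held at most 1 mutant plant each. This relation was examined after the scores were seen and computed in each of the forms given here, with no correction for their number. It is given as a value.

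The 2 mutant plants titled lbf were set against the 4 titled lbf1. With limma, 0 of 28267 probes were called, and 2301 had an unadjusted p under 0.05. The highest of the other splits of the 6 plants called 1, and 15 splits are too few for a share under 0.05.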
